A study of Canis lupus familiaris with 12 samples.

How the data were processed

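One Cy3-labelled RNA sample of MDCK cells was hybridised to each of 12 canine 44K arrays, 4 biological replicates for each of 3 stages per the labels (monolayer, extension at 72 h of co-culture, tubule at 144 h). RNA was extracted with Trizol and purified on spin columns, then amplified and labelled with a kit for low RNA input, per the labels. The scanner files hold spot and background intensity as Agilent Feature Extraction wrote it (9.1 in the processing notes, 9.5.1.1 per the file headers), and their processed signal is an intensity that was background-subtracted and detrended within each array per the file headers. Values at the level of background are replaced there by a small surrogate. No scaling between arrays had been applied to these files. The deposited value table is in log2 units of the median spot signal, and its 12 columns have nearly the same quantiles (largest difference 0.037), as after quantile normalization between arrays. Column medians of the deposited table were 6.71 for each of the 12 columns (6.7065 to 6.7131), so the values are not centred per gene. Each column was found to match 1 scanner array of its own stage (r = 0.9985 to 0.9999), but for 8 of the 12 columns that array carries another replicate number. The table's scale and direction were read off this match, and which of the replicate numbers is the right one stays unknown. The scanner files were used for the results, and the table served as an alternative.

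Stages, replicate numbers and slides were taken from the labels and file headers. Samples were grouped by stage, and 0 columns belonged to no sample. Of 42034 probes other than controls, 11167 received a gene symbol (10933 symbols) and 30867 had none. Names came from the gene identifier that the files give (10117 probes), an accession (529), the files' symbol (347), a synonym (170), a symbol or a gene identifier in the description (122 and 115) or an older symbol (9), matched to the annotation of a current dog genome, and 156 probes kept the files' own name. A name made of LOC and a number was not counted as a symbol. The probes without a symbol thus include 30469 with no name and those with such a LOC name. Where a symbol differs from the array's own, the array's name is given. Probes without a symbol stayed in the tests under their own identifier and were not named.

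Processed signal was put on the log2 scale and the array's 75th percentile over the probes other than controls was subtracted. A probe was tested where it was well above background on all 4 arrays of at least 1 stage, which held for 23301 probes, and 607 of these were left out for outlier marks on some array (728 probes and 2134 spots of all were marked). The 22694 remaining probes gave 22619 features, 1 per gene, represented by the brightest tested probe. Of these, 72 genes had several tested probes, and those of SEC61G were called in opposite directions at tubule over monolayer and tubule over extension. Signal over background limits which genes can be measured, and the number of arrays limits the precision. The 3 contrasts (extension against monolayer, tubule against monolayer, tubule against extension) were fitted on all 12 arrays in limma 3.58.1 (lmFit and eBayes, 9 residual and 3.48 prior degrees of freedom) in R 4.3.3 with the data.table package (version 1.17.8). Calls are at a Benjamini-Hochberg adjusted p under 0.05. A feature peaked or dipped at extension where both steps were called in opposite directions. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for reading, tables and figures.

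Gene lists, 30 in number, were tested with limma's camera (preset correlation of 0.01, lists with at least 5 measured members, Benjamini-Hochberg within a contrast), and members were also counted by the gene test and adjusted over the list alone. SE is that of the moderated fit. Where a gene was not well above background on any array of 1 stage, the fold is a lower bound, computed with that stage's values raised to at least the lowest signal well above background on the same array. The same raising was applied, after the values were seen, to changes where 1 to 3 arrays of the dimmer stage were well above background. The contrasts, tests, gene lists, named-gene rule and the first set of alternatives were chosen before the data were examined.

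Genes named are, per contrast, the 10 with a symbol with the largest rise and the 10 with the largest fall among called features with no overlap of 4 against 4 arrays and the probe well above background on all 4 arrays of the higher stage. For peaking and dipping features they are 10 each by the smaller of the 2 changes, and per list up to 4 members with the smallest adjusted p. TNS4, MET, STAT3, HGF, MMP13, MMP14, CDH1, VIM, PODXL, KRT18, COL1A1, COL1A2 and COL3A1 are given whatever their result. Of 393 gene and contrast pairs that this rule named and that were called, 195 are printed and the others are not reported here. This selection was made after their values were seen, and it left out every pair whose call ended with 1 array left out. Some genes are also given in a contrast other than the one that named them.

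On simulated data with the arrays' own spread (22619 features, 50 changed by each amount), calls in extension against monolayer recovered 8%, 60%, 88% and 98% of log2 changes of 0.5, 1, 2 and 3. Calls in tubule against extension recovered 4%, 54%, 90% and 98%, and unchanged features made up 3.05% and 2.38% of the calls. The simulated noise was independent between arrays and few features were changed. In the data 23.5% to 24.4% of features were called per contrast and arrays of a slide deviate together. These rates therefore need not hold for the data. Alternatives tried were normexp with an offset of 50 on local background, quantile normalization, median centring, the deposited values, no filter on dim probes, a filter over all 12 arrays and the mean of a gene's probes. Further ones were replicate number or slide as a block, trended and robust variance, array weights, 2 stages at a time, an adjusted p under 0.01, a change of at least 2-fold, each array left out in turn, an estimated correlation and fry. Alternatives chosen after seeing the data were leaving out slide 3, keeping marked probes, normexp on median background, an estimated correlation with slide as a block and a background of named genes for the list test. A block of scan was not run apart, because each slide is 1 scan.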

Results

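Madin-Darby canine kidney (MDCK) cells, a dog kidney epithelial line, were grown as a monolayer on thick collagen and then co-cultured with MRC-5 human lung fibroblasts, under which the monolayer sends out extensions and later forms tubules. RNA was taken at 3 stages, the monolayer before co-culture, the extension stage at 72 h and the tubule stage at 144 h, with 4 biological replicates of each, and each of the 12 samples was hybridised to its own 1-colour canine array. On each array 42034 probes other than controls were measured, of which 51.7% (monolayer 4) to 62.3% (extension 4) were well above background. The 75th percentile of processed signal lay between 604.8 and 853.4, and 0 to 19 spots were saturated. The number of arrays limits the precision of what follows. Signal was tested for 22619 features, 7710 of them with a gene symbol.

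The arrays lay on 3 slides of 4 arrays, and each slide held all 3 stages, though not in equal numbers. Slide 1 held monolayer 1, extension 1, extension 2 and tubule 1. Slide 2 held monolayer 2, extension 3, tubule 2 and tubule 3. Slide 3 held monolayer 3, monolayer 4, extension 4 and tubule 4. The main fit has no slide term. The first principal component took 32.5% of the variance, with 64.1% of its scores' variance between slides and 52.3% between stages. The second took 28.1%, with 87% between stages and 9.2% between slides. Because slide and stage both separated the arrays, values are also given with slide as a block and within slides. Tubule 4 held 15 of the 33 values, over the 140 named genes and the measures of array quality, that lay far from the other 3 of their stage.

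**Figure D1:**
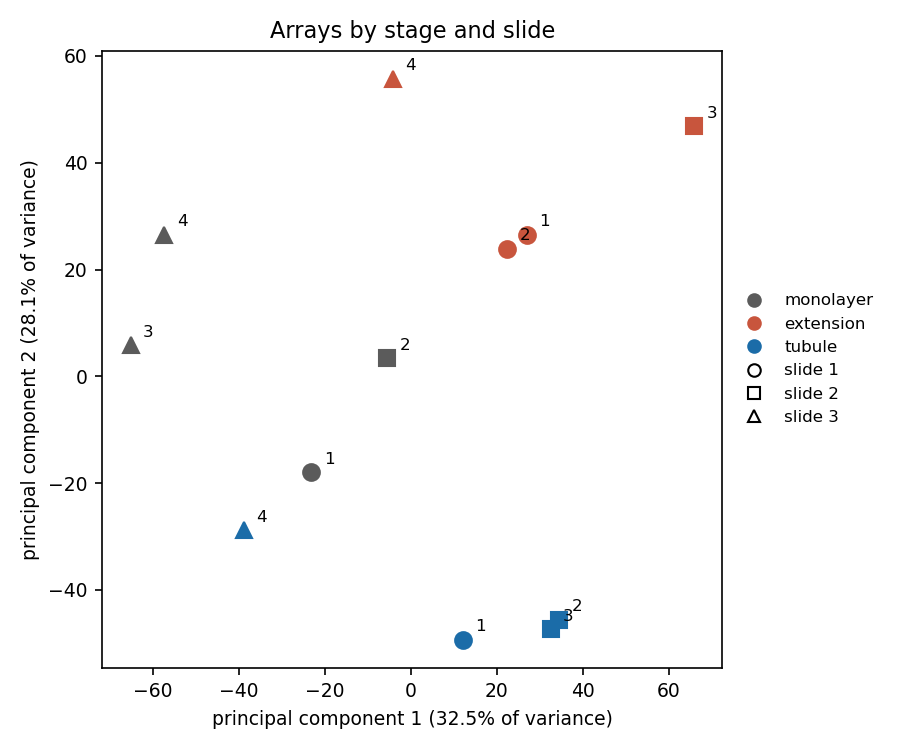
Scores of the 12 arrays on principal components 1 (32.5% of variance) and 2 (28.1%) of log2 signal over the tested features, with colour for stage and marker shape for slide. The 4 tubule arrays lie below the other 8 on component 2, where monolayer and extension arrays overlap, and slide 3 lies to the left on component 1 within each stage.

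The comparisons ask which transcripts change over time together with the extension and the tubule stage. No monolayer without fibroblasts was sampled at 72 h or 144 h, so stage, culture time and co-culture cannot be told apart. Among the genes described whatever their result, TNS4 (tensin 4, a focal adhesion adaptor protein; array name LOC491012; probe at chromosome 9, 14818752 to 14819330 as the array's annotation gives it, genome build not named) rose from monolayer to extension by 1.89 ± 0.17 on the log2 scale (3.7-fold, SE, n = 4 arrays per stage, adjusted p = 9.17e-06) and fell from extension to tubule by 1.53 ± 0.17 (adjusted p = 8.49e-05). The tubule did not differ detectably from the monolayer (0.36 ± 0.17, adjusted p = 0.158). With slide as a block the rise was 2.01, and within slides it was 1.97, 2.06 and 2.06. STAT3, a cytokine-activated transcription factor, rose by 0.67 ± 0.11 at extension (adjusted p = 0.000892) and stood 0.74 ± 0.11 above the monolayer at the tubule stage (adjusted p = 0.00041), and centring on the median ended the call at extension (0.45). No change was called at extension for MET, the receptor of hepatocyte growth factor (0.36 ± 0.21), for the membrane protease MMP14 (0.27 ± 0.14) or for E-cadherin CDH1 (0.28 ± 0.13). Nor was one called for vimentin VIM (0.03 ± 0.15), podocalyxin PODXL (0.45 ± 0.33) or keratin KRT18 (0.12 ± 0.14), or for any of these 6 in the other contrasts. Blocked by slide, calls were made for MET (0.44 at extension and 0.70 at the tubule stage against the monolayer) and MMP14 (0.34 and 0.31). The block also gave calls for VIM (-0.29 at tubule over monolayer and -0.39 over extension), KRT18 (-0.28 at tubule over extension) and TNS4 (0.45 at tubule over monolayer). VIM was also called at tubule over extension without tubule 4 (-0.48) or monolayer 4 (-0.40), and at tubule over monolayer without tubule 4 (-0.45). Probes of HGF, MMP13, COL1A1, COL1A2 and COL3A1 were well above background on 0 of the 12 arrays.

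At an adjusted p under 0.05, 2386 features were higher and 2935 lower at extension than in the monolayer, 2314 higher and 3196 lower at the tubule stage than in the monolayer, and 2885 higher and 2570 lower at the tubule stage than at extension (23.5%, 24.4% and 24.1% of those tested). Of the 22619 features, 23.4%, 28.4% and 25.8% had no overlap of the 4 against 4 arrays, where chance gives 2.86% for exchangeable arrays. These arrays are not exchangeable, since arrays of a slide deviate together. At least 2-fold changes made up 676 and 719, 571 and 690, and 1118 and 393 of these calls. The median change of all tested features was 0.03, 0.02 and -0.10 in the 3 contrasts. Centring each array on its median in place of its 75th percentile moved these medians to -0.18, -0.14 and -0.06, and the share of calls that were higher from 44.8%, 42.0% and 52.9% to 20.3%, 20.6% and 66.5%. The share of higher calls at tubule over extension was 40.9% with normexp on median background. Blocked by slide, the calls were 5583 higher and 5006 lower, 4819 and 4757, and 4968 and 6665. Without 1 array the 2570 features lower at tubule than at extension were 1627 (without tubule 1), 1683 (tubule 2) or 1568 (tubule 3).

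From monolayer to extension, genes of ERK and STAT3 output, extracellular proteases and the unfolded protein response rose as groups by camera, while genes of mitosis and the primary cilium fell. None of these 6 group calls was made with an estimated correlation and no slide block (adjusted p from 0.0934 to 0.48). With slide also as a block, 5 of the 34 list calls over all contrasts were kept, and which lists these were is not given here. Unless a slide block is named, values given below with an estimated correlation come from the fit without a slide term. SLC6A14, an amino acid transporter, rose at least 50.7-fold (adjusted p = 2.16e-08, n = 4 arrays per stage), the bound used for a gene that was not well above background on any array of 1 stage. SLC46A2, a solute carrier (array name TSCOT), rose by 5.04 ± 0.14 on the log2 scale (SE, adjusted p = 9.5e-10), and MME, the cell surface peptidase neprilysin, by 4.17 ± 0.17 (adjusted p = 1.54e-08). PDZK1, a scaffold protein of brush border transporters, fell by 3.82 ± 0.15 (adjusted p = 1.54e-08), and the carboxylesterase CES1 (array name CESDD1) fell by 5.29 ± 0.35 (adjusted p = 5.62e-07), with 2 of 4 extension arrays well above background. The mitotic kinase NEK2 fell by 1.5 ± 0.11 (adjusted p = 1.16e-06).

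Other leading rises at extension were DSG3, a desmosomal cadherin well above background on 2 of 4 monolayer arrays (3.96 ± 0.21), the microsomal glutathione transferase MGST1 (3.62 ± 0.19), the interleukin 13 receptor IL13RA2 (3.51 ± 0.19) and the heparan sulfate enzyme NDST1 (3.46 ± 0.34). The inflammatory caspase CASP4 (array name CASP1) was at least 5.3-fold higher (adjusted p = 4.96e-09), the O-glycan enzyme GCNT1 at least 3.95-fold (adjusted p = 4.49e-08) and the proprotein convertase PCSK2 at least 2.18-fold (adjusted p = 3.69e-07). Falls also included the actin binding protein AVIL (-3.95 ± 0.49) and FASTKD2, a mitochondrial RNA binding protein (-3.52 ± 0.55). Lower too were the acyl-CoA synthetase ACSL6 (-2.96 ± 0.38) and TM4SF5 (-2.86 ± 0.20). So were the retinol dehydrogenase RDH16 (-2.80 ± 0.16), SAMD11 (-2.74 ± 0.14) and TINAG, a tubular basement membrane protein (-2.73 ± 0.16), and alpha-fetoprotein AFP was at least 1.45-fold lower (adjusted p = 2.48e-06). Adjusted p of the genes in this paragraph given with a log2 change lay between 8.04e-08 and 0.000622. At extension 1 of 4 arrays was well above background for AVIL, ACSL6 and FASTKD2, and 2 of 4 for RDH16 and TINAG, so that the sizes of these falls rest in part on values near background. With such values raised to the lowest signal well above background on the same array, the falls were 2.6 for AVIL, 2.40 for ACSL6, 1.86 for FASTKD2, 2.67 for RDH16 and 2.68 for TINAG. Of the 19 changes given here for a dimmer stage with 1 to 3 such arrays, the others shrank by at most 0.76 in this way.

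Camera called the ERK and STAT3 output, protease, integrin, cell junction and epithelial-mesenchymal lists upward at extension. Over the 3 contrasts it made 34 calls. Random draws of the 12 arrays into 3 stages gave a median of 18 (99 draws, highest 33). Of 29 lists tested at extension, camera called 16. With an estimated correlation it called 0, with 6 lists at an unadjusted p under 0.05, and fry, another set test, called 14. Of 15 measured ERK MAP kinase output genes, 11 were higher, 0 lower and 4 not called (13 higher and 0 lower adjusted over the list alone), and camera gave adjusted p = 4.21e-07 (adjusted p = 0.0934 with an estimated correlation). Among them were the immediate early genes IER3 (1.40 ± 0.12) and FOS (1.89 ± 0.19) and cyclin D1 CCND1 (1.08 ± 0.16). The median change of 0.83 was 0.85 with slide as a block and 0.99, 0.88 and 0.89 within slides. Of 16 STAT3 target genes 10 were higher, 1 lower and 5 not called (11 higher and 2 lower adjusted over the list alone), and camera gave adjusted p = 0.000182 (adjusted p = 0.0934 with an estimated correlation). The protease inhibitor TIMP1 (array name TIMP-1) stood at 2.70 ± 0.16, the oncostatin M receptor OSMR at 2.19 ± 0.14 and, among those lower, the survivin gene BIRC5 at -1.60 ± 0.18. Extracellular proteases and inhibitors counted 23 measured, of which 10 were higher, 1 lower and 12 not called (12 higher and 1 lower adjusted over the list alone), and camera gave adjusted p = 4.88e-06 (adjusted p = 0.225 with an estimated correlation). They included tissue plasminogen activator PLAT (2.90 ± 0.13) and MMP28 (1.43 ± 0.14). In the 25 integrin and focal adhesion genes 8 were higher, 2 lower and 15 not called (11 higher and 3 lower adjusted over the list alone), and camera gave adjusted p = 0.00677 (adjusted p = 0.432 with an estimated correlation). ITGA2 stood at 1.35 ± 0.13, ITGA3 at 1.12 ± 0.15 and ITGB8 at -1.36 ± 0.19. Cell junction genes counted 29, of which 6 were higher, 1 lower and 22 not called (6 higher and 1 lower adjusted over the list alone), and camera gave adjusted p = 0.00392 (adjusted p = 0.487 with an estimated correlation). DSG3 and the nectin NECTIN1 (array name prr1; 1.01 ± 0.15) were among them. For epithelial-mesenchymal transition, 6 were higher, 3 lower and 12 not called (8 higher and 3 lower adjusted over the list alone) of 21, and camera gave adjusted p = 0.00398 (adjusted p = 0.18 with an estimated correlation). The transcription factors SNAI1 (1.96 ± 0.18, 1 of 4 monolayer arrays well above background) and SNAI2 (2.12 ± 0.21) and the hyaluronan receptor CD44 (1.5 ± 0.23) rose. N-cadherin CDH2 (array name NCAD) was at least 2.21-fold higher (adjusted p = 0.000577), and S100A4 (array name MTS1) stood at -0.78 ± 0.15.

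Glycolysis, unfolded protein response, kidney transport, chemokine and WNT lists were called upward by camera as well, none of them with an estimated correlation. Fry made no call for the chemokine list (adjusted p = 0.0643). Glycolysis and hypoxia genes counted 24, of which 9 were higher, 0 lower and 15 not called (12 higher and 0 lower adjusted over the list alone), and camera gave adjusted p = 9.16e-06 (adjusted p = 0.42 with an estimated correlation). The prolyl hydroxylase EGLN3 stood at 2.69 ± 0.22, PFKFB3 at 1.80 ± 0.15 and the glucose transporter SLC2A1 at 1.22 ± 0.17. Of 23 genes of the unfolded protein response and amino acid stress 13 were higher, 0 lower and 10 not called (14 higher and 1 lower adjusted over the list alone), and camera gave adjusted p = 0.000128 (adjusted p = 0.48 with an estimated correlation). The chaperones HSPA5 (1.02 ± 0.13) and HYOU1 (0.90 ± 0.13) rose. Among 31 kidney tubule transport and differentiation genes 11 were higher, 4 lower and 16 not called (12 higher and 5 lower adjusted over the list alone), and camera gave adjusted p = 0.0203 (adjusted p = 0.569 with an estimated correlation). The sodium channel subunit SCNN1B (2.25 ± 0.11) and carbonic anhydrase CA12 (2.25 ± 0.15) rose, and the cation transporter SLC22A2 (-1.44 ± 0.18) fell. The kidney list's median of 0.26 was 0.17 without extension 4. Of 18 chemokine, cytokine and inflammation genes 9 were higher, 3 lower and 6 not called (10 higher and 4 lower adjusted over the list alone), and camera gave adjusted p = 0.0163 (adjusted p = 0.739 with an estimated correlation). Cyclooxygenase 2 PTGS2 stood at 1.57 ± 0.19, the receptor TLR4 at 1.24 ± 0.16 and the apoptosis inhibitor BIRC3 at -1.38 ± 0.17. In the WNT pathway 4 were higher, 0 lower and 22 not called (4 higher and 0 lower adjusted over the list alone) of 26, and camera gave adjusted p = 0.0203 (adjusted p = 0.225 with an estimated correlation). The receptor FZD2 (1.29 ± 0.13) and the transcription factor TCF7 (1.33 ± 0.20) were among its members.

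Proliferation, cilium, oxidative and sterol lists were called downward by camera at extension, none of them with an estimated correlation. Fry made no call for S phase (adjusted p = 0.0993) or oxidative phosphorylation (adjusted p = 0.093). Of 36 G2/M and mitosis genes 0 were higher, 32 lower and 4 not called (0 higher and 33 lower adjusted over the list alone), and camera gave adjusted p = 2.43e-23 (adjusted p = 0.0934 with an estimated correlation). They included NEK2, the kinesin KIF20A (-1.61 ± 0.12) and the spindle protein ASPM (-2.33 ± 0.19). Their median change of -1.30 was -1.25 with slide as a block and -1.26, -1.26 and -1.32 within slides. Of 28 S phase and DNA replication genes 1 was higher, 7 lower and 20 not called (1 higher and 7 lower adjusted over the list alone), and camera gave adjusted p = 0.00494 (adjusted p = 0.739 with an estimated correlation). Cyclin E2 CCNE2 stood at -1.06 ± 0.14 and the replication factor MCM10 at -1.16 ± 0.18. Primary cilium and intraflagellar transport counted 36 genes, of which 0 were higher, 14 lower and 22 not called (0 higher and 16 lower adjusted over the list alone), and camera gave adjusted p = 0.000154 (adjusted p = 0.42 with an estimated correlation). IFT88 stood at -1.55 ± 0.21, the dynein chain DNAI1 at -1.40 ± 0.14 and IFT80 at -1.0 ± 0.20. Of 32 oxidative phosphorylation genes 0 were higher, 9 lower and 23 not called (0 higher and 10 lower adjusted over the list alone), and camera gave adjusted p = 0.000535 (adjusted p = 0.739 with an estimated correlation). The complex I subunit NDUFA5 stood at -0.64 ± 0.13, and the list's median of -0.33 was -0.22 without monolayer 4. Cholesterol synthesis had 22 measured genes, of which 1 was higher, 9 lower and 12 not called (1 higher and 10 lower adjusted over the list alone), and camera gave adjusted p = 0.000325 (adjusted p = 0.487 with an estimated correlation). HMGCS1 stood at -1.23 ± 0.12 and the desaturase SCD at -0.89 ± 0.14.

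No shift was called at extension for 13 lists. By single genes, fibroblast markers gave 2 higher and 1 lower of 11 (5 and 1 adjusted over the list alone). The growth factor receptor PDGFRA was at least 2.08-fold higher (adjusted p = 0.000661, 3 of 4 extension arrays well above background), FBLN5 stood at 0.97 ± 0.16 and smooth muscle actin ACTA2 at -0.63 ± 0.16, a call that ended without slide 3. Basement membrane and matrix gave 4 higher and 6 lower of 23 (4 and 8 adjusted over the list alone), including the laminin chain LAMA3 (2.16 ± 0.16). Actin, contractility and migration gave 5 higher and 2 lower of 25 (6 and 3 adjusted over the list alone), and polarity and lumen formation 7 higher and 4 lower of 33 (7 and 4 adjusted over the list alone). Growth factor receptors and ligands gave 3 higher and 4 lower of 22 (4 and 5 adjusted over the list alone), and p53 targets and cell cycle inhibitors 3 higher and 2 lower of 20 (3 and 2 adjusted over the list alone). The interferon response gave 3 higher and 3 lower of 18 (3 and 3 adjusted over the list alone) and heat shock and oxidative stress 6 higher and 6 lower of 18 (6 and 8 adjusted over the list alone). For the Notch pathway the counts were 2 higher and 0 lower of 11 (0 and 0 adjusted over the list alone) and for the TGF-beta and BMP pathway 5 higher and 5 lower of 35 (6 and 5 adjusted over the list alone). YAP targets gave 2 higher and 5 lower of 14 (2 and 5 adjusted over the list alone), ribosomal proteins 0 higher and 4 lower of 32 (0 and 3 adjusted over the list alone) and common reference genes 0 higher and 2 lower of 10 (0 and 2 adjusted over the list alone). Immune and endothelial cell markers had 3 measured members, too few for the set test, of which 0 were called. Camera's adjusted p of the 13 lists lay between 0.0653 and 0.963, and of these lists fry called fibroblast markers, upward (adjusted p = 0.000287, median 0.45, 0.26 with slide as a block and -8e-04 under normexp with local background). Median, mean and test differed in sign for 5 of them (growth factors, YAP targets, basement membrane, interferon response and reference genes). At extension and blocked by slide, 16 of the 16 called lists and 87 of the 87 genes named and called were called in the same direction, and 16 lists and 87 genes kept their sign within each of the 3 slides. Over all features the block kept 99.9% of the calls in each of the 3 contrasts, so the genes' agreement with it is not particular to them. For genes named in this contrast by the rule of no overlap between arrays, the sign within slides was fixed by that rule. Medians of the called lists moved by at most 0.11 with the block and by at most 0.19 within a slide, and the genes' log2 changes by at most 0.35 (FASTKD2) and 2.12 (AVIL). The call ended under at least 1 other alternative for 5 lists (epithelial-mesenchymal transition, S phase, chemokines, oxidative phosphorylation and WNT), with adjusted p from 3.43e-37 to 0.606 over the 16 lists. Of the genes, 65 of 87 kept their call under normexp with local background (PDGFRA turned in sign), 87 under normexp with median background and 86 with median centring (lost for STAT3). Local background ended the calls of ACTA2, CASP4, CDH2, CDKN2C, CFTR, CGREF1, EPSTI1, GCNT1, HYOU1, IFIT2 and IL1RN. It also ended those of NDUFA5, NECTIN1, PCK1, PCSK2, PTGS2, RASA3, S100A4, SNAI1, TCF7 and TLR4.

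**Figure D2:**
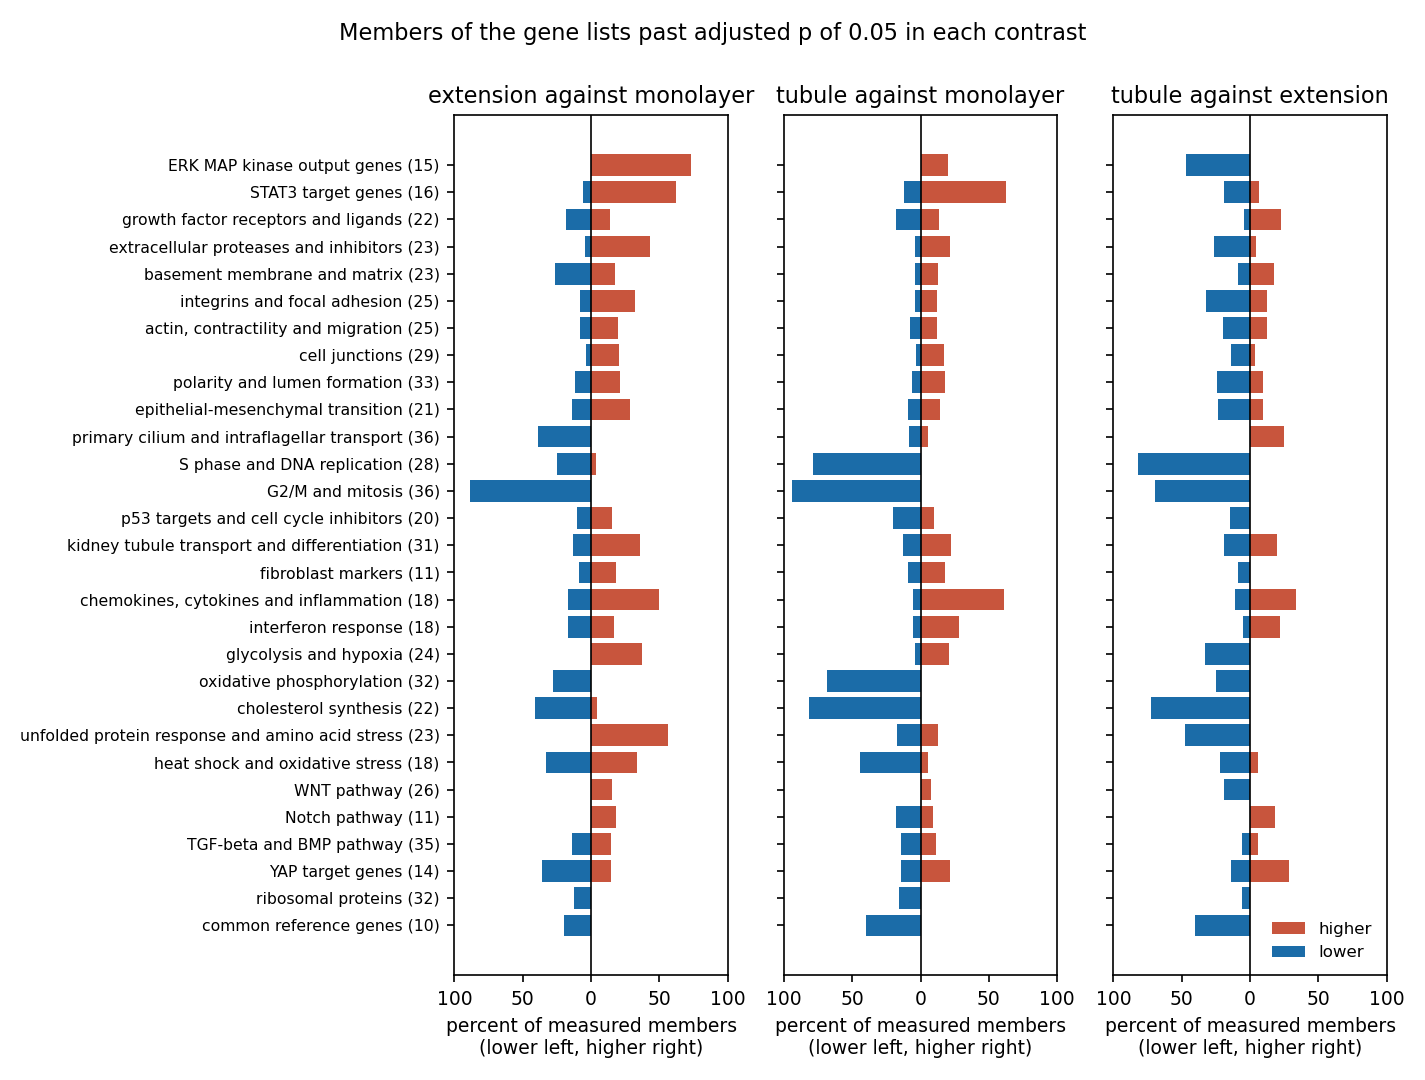
Percent of each gene list's measured members called higher (right) and lower (left) in the 3 contrasts at an adjusted p under 0.05, for 29 lists. The bars of G2/M and mitosis point to lower in all 3 contrasts, and those of primary cilium genes turn from lower at extension to higher at tubule over extension.

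Against the monolayer, camera called the chemokine list upward at the tubule stage at 144 h and the mitotic, replication, oxidative and sterol lists downward. None of these 5 calls was made with an estimated correlation and no slide block (adjusted p from 0.0709 to 0.613). MME stood 3.97 ± 0.17 above the monolayer on the log2 scale (SE, n = 4 arrays per stage, adjusted p = 3e-08), and C1S, a complement protease, 3.50 ± 0.15 (adjusted p = 3e-08). The chemokine CCL7 was at least 8.4-fold higher (adjusted p = 9.61e-06), and the chemokine CCL2 rose by 2.08 ± 0.19 (adjusted p = 6.67e-06). CES1 fell by 5.33 ± 0.35 (adjusted p = 5.53e-07), with 2 of 4 tubule arrays well above background, and the cyclin gene CCNB3 fell by 3.09 ± 0.13 (adjusted p = 3e-08). CENPA, the centromeric histone, fell by 2.74 ± 0.13 (adjusted p = 5.57e-08).

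Further rises at the tubule stage were SLC46A2 (3.26 ± 0.14, adjusted p = 3e-08) and the elastase inhibitor PI3 (3.17 ± 0.17, adjusted p = 1.05e-07). Against a monolayer not well above background, SLC6A14 was at least 5.41-fold higher (adjusted p = 2.28e-06) and the bile acid conjugating enzyme BAAT at least 3.52-fold (adjusted p = 3.07e-07). By the same bound the adaptor FYB1 was at least 3.12-fold (adjusted p = 5.21e-08), interstitial collagenase MMP1 at least 2.57-fold (adjusted p = 1.94e-06) and the interferon-induced GTPase GBP5 at least 3.31-fold higher (adjusted p = 8.59e-06). FASTKD2 was at least 3.88-fold lower (adjusted p = 0.000262). Other falls were the spindle protein DLGAP5 (-2.96 ± 0.18), the linker histones H1-1 (-2.93 ± 0.37) and H1-5 (-2.89 ± 0.32), the fatty acid binding protein FABP1 (array name FABP; -2.92 ± 0.17), and the mitotic genes CDCA2 (-2.78 ± 0.15) and SPAG5 (-2.78 ± 0.20), with adjusted p between 1.03e-07 and 0.000129.

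At the tubule stage against the monolayer, proliferation, sterol, oxidative and ribosomal lists were called downward by camera. Camera called 9 of the 29 lists, and fry called 12. With an estimated correlation camera called 0, with 4 lists at an unadjusted p under 0.05. Of 36 G2/M and mitosis genes 0 were higher, 34 lower and 2 not called (0 higher and 34 lower adjusted over the list alone), and camera gave adjusted p = 6.43e-35 (adjusted p = 0.0709 with an estimated correlation). NEK2 stood at -2.50 ± 0.11, KIF20A at -2.55 ± 0.12 and the spindle assembly factor TPX2 at -2.52 ± 0.13. The median of -2.08 was -1.98 with slide as a block and -1.90, -2.12 and -1.88 within slides. Of 28 S phase and DNA replication genes 0 were higher, 22 lower and 6 not called (0 higher and 24 lower adjusted over the list alone), and camera gave adjusted p = 2.49e-17 (adjusted p = 0.322 with an estimated correlation). The polymerase POLE stood at -2.30 ± 0.17 and the helicase subunit MCM4 at -1.52 ± 0.12. Cholesterol synthesis counted 22 genes, of which 0 were higher, 18 lower and 4 not called (0 higher and 19 lower adjusted over the list alone), and camera gave adjusted p = 2.92e-13 (adjusted p = 0.293 with an estimated correlation). HMGCS1 (-1.85 ± 0.12), FDPS (-1.85 ± 0.17) and LSS (-1.55 ± 0.12) were among those lower. Oxidative phosphorylation counted 32, of which 0 were higher, 22 lower and 10 not called (0 higher and 26 lower adjusted over the list alone), and camera gave adjusted p = 4e-11 (adjusted p = 0.463 with an estimated correlation). NDUFA5 stood at -1.09 ± 0.13 and cytochrome c1 CYC1 at -1.17 ± 0.17. Of 32 ribosomal protein genes 0 were higher, 5 lower and 27 not called (0 higher and 5 lower adjusted over the list alone), and camera gave adjusted p = 0.0112 (adjusted p = 0.751 with an estimated correlation). RPL7 stood at -0.95 ± 0.14 and RPSA at -0.69 ± 0.12. The ribosomal median of -0.18 was -0.09 without monolayer 4, which ended the call (adjusted p = 0.0713, with adjusted p from 0.00114 to 0.759 over all alternatives). Quantile normalization, the deposited values, normexp on local background, leaving out slide 3 and a background of named genes ended it too.

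Against the monolayer, camera called 4 lists upward at the tubule stage. Of 18 chemokine, cytokine and inflammation genes 11 were higher, 1 lower and 6 not called (11 higher and 2 lower adjusted over the list alone), and camera gave adjusted p = 9.03e-05 (adjusted p = 0.613 with an estimated correlation). They included CCL2, CCL7, TLR4 (1.66 ± 0.16) and the chemokine CCL20 (1.35 ± 0.15). The chemokine list's median of 0.62 was 0.73 with slide as a block and 0.60, 0.70 and 0.89 within slides, and 0.52 with the 3 dim members at their bound. Of 16 STAT3 target genes 10 were higher, 2 lower and 4 not called (11 higher and 2 lower adjusted over the list alone), and camera gave adjusted p = 0.000693 (adjusted p = 0.202 with an estimated correlation). OSMR stood at 2.07 ± 0.14, TIMP1 at 1.78 ± 0.16 and BIRC5 at -2.57 ± 0.18. Their median of 0.63 was 0.58 with the 1 dim member at its bound and -0.01 under normexp with local background, where the test still pointed upward. For ERK MAP kinase output genes 3 were higher, 0 lower and 12 not called (3 higher and 0 lower adjusted over the list alone) of 15, and camera gave adjusted p = 0.0108 (adjusted p = 0.463 with an estimated correlation). IER3 stood at 0.64 ± 0.12 and FOS at 0.72 ± 0.19. Of 23 extracellular proteases and inhibitors 5 were higher, 1 lower and 17 not called (5 higher and 1 lower adjusted over the list alone), and camera gave adjusted p = 0.0132 (adjusted p = 0.613 with an estimated correlation). PLAT (2.41 ± 0.13) and TIMP3 (0.85 ± 0.16) were among those higher.

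No shift was called at the tubule stage against the monolayer for 20 lists (camera's adjusted p between 0.0587 and 0.976). With slide as a block camera did call 2 of them, glycolysis and hypoxia upward (median 0.25 against 0.18, adjusted p = 0.0103 against 0.0621, from 0.000131 to 0.751 over the alternatives) and common reference genes downward (median -0.29 against -0.39, adjusted p = 0.0436 against 0.0621, from 0.018 to 0.463 over the alternatives). Fry called fibroblast markers (adjusted p = 0.00442) and the kidney list (adjusted p = 0.0288) upward and heat shock and oxidative stress (adjusted p = 0.00604) and reference genes downward. For 7 of them median, mean and test differed in sign (the Notch, TGF-beta and WNT pathways, YAP targets, actin, polarity and p53 targets). ZEB1, a transcription factor of the epithelial-mesenchymal list (3 higher and 2 lower of 21, or 3 and 2 adjusted over the list alone), rose by 2.10 ± 0.23, with 3 of 4 monolayer arrays well above background. The integrin ITGB6 stood at 1.08 ± 0.12 in its list (3 higher and 1 lower of 25, or 3 and 1 adjusted over the list alone), and the claudin CLDN7 at -1.22 ± 0.22 among cell junctions (5 higher and 1 lower of 29, or 5 and 1 adjusted over the list alone). The sodium, potassium and chloride cotransporter SLC12A2 stood at 1.22 ± 0.15 in the kidney list (7 higher and 4 lower of 31, or 7 and 5 adjusted over the list alone). Common reference genes gave 0 higher and 4 lower of 10 (0 and 4 adjusted over the list alone), with a median of -0.39, further down than that of ribosomal proteins (-0.18). Camera without the block made no call for them (adjusted p = 0.0621, from 0.018 to 0.463 over the alternatives), and fry did (adjusted p = 0.000844). PDGFRA of the fibroblast markers was at least 1.47-fold higher (adjusted p = 0.00489, 2 higher and 1 lower of 11, or 2 and 1 adjusted over the list alone), and the cilium list gave 2 higher and 3 lower of 36 (2 and 3 adjusted over the list alone). At tubule over monolayer and blocked by slide, 9 of the 9 called lists and 56 of the 56 genes named and called were called in the same direction, and 9 lists and 56 genes kept their sign within each of the 3 slides. That sign was again fixed for genes named in this contrast by the rule of no overlap. Medians of the called lists moved by at most 0.11 with the block and by at most 0.27 within a slide, and the genes' log2 changes by at most 0.30 (FASTKD2) and 1.12 (PDGFRA). The call ended under at least 1 other alternative for ribosomal proteins, with adjusted p from 8.11e-56 to 0.759 over the 9 lists. Of its genes, 44 of 56 kept their call under normexp with local background (PDGFRA turned in sign), 55 under normexp with median background and 54 with median centring (lost for FOS and IER3). Local background ended the calls of BAAT, CCL20, CCL7, FYB1, GBP5, IFIT2, MMP1, SLC6A14, TIMP3, TLR4 and ZEB1.

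From extension to tubule, camera called the primary cilium list upward, though 27 of its 36 genes were not called singly, and the lists of the unfolded protein response, sterol synthesis and the cell cycle downward. None of these 5 calls was made with an estimated correlation and no slide block (adjusted p from 0.48 to 0.516). PDZK1 rose by 3.28 ± 0.15 on the log2 scale (SE, n = 4 arrays per stage, adjusted p = 1.09e-07) after its fall at extension, and CCL2 rose by 3.18 ± 0.19 (adjusted p = 6.49e-07). The chloride channel CFTR rose by 3.01 ± 0.32 (adjusted p = 5.19e-05), with 1 of 4 extension arrays well above background. MGST1 fell by 3.48 ± 0.19 (adjusted p = 4.31e-07), SLC6A14 fell by 3.23 ± 0.30 (adjusted p = 2.12e-05), and CASP4 was at least 5.36-fold lower (adjusted p = 7.28e-09).

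Other rises were the chemokine CCL8 (2.98 ± 0.28), TXNIP, an inhibitor of thioredoxin (2.87 ± 0.19), the small GTPase RERG (2.81 ± 0.18), EPSTI1 (2.6 ± 0.35), the class II histocompatibility gene DLA-DQB1 (2.57 ± 0.23) and the matrix protein THBS1 (2.51 ± 0.18), with adjusted p between 9.33e-07 and 0.000239. BAAT was at least 3.53-fold higher (adjusted p = 1.37e-06) and MMP1 at least 2.58-fold (adjusted p = 0.000133). Among the falls, TMEM45B changed by -2.75 ± 0.15 (adjusted p = 4.31e-07). Against a tubule stage not well above background, the dioxin-inducible monooxygenase CYP1A1 was at least 5.49-fold lower (adjusted p = 0.00049), the interleukin 1 receptor antagonist IL1RN at least 3.75-fold (adjusted p = 2.98e-05), and CGREF1 at least 3.5-fold (adjusted p = 2.09e-05). The gluconeogenic enzyme PCK1 (array name PEPCK) was at least 2.34-fold (adjusted p = 2.54e-06) and the transcription factor TFAP2C at least 2.13-fold lower (adjusted p = 4.71e-05).

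From extension to tubule, camera called 9 of the 29 lists and fry 16. With an estimated correlation camera called 0, and 1 list had an unadjusted p under 0.05. Of 36 primary cilium and intraflagellar transport genes 9 were higher, 0 lower and 27 not called (9 higher and 0 lower adjusted over the list alone), and camera gave adjusted p = 4.97e-05 (adjusted p = 0.48 with an estimated correlation). IFT88 stood at 1.58 ± 0.21, DNAI1 at 0.89 ± 0.14 and the ciliopathy genes CEP290 and TMEM67 at 0.95 ± 0.19 and 0.89 ± 0.18. The cilium list's median of 0.31 was 0.32 with slide as a block and 0.28, 0.33 and 0.31 within slides. Of 28 S phase and DNA replication genes 0 were higher, 23 lower and 5 not called (0 higher and 25 lower adjusted over the list alone), and camera gave adjusted p = 2.41e-12 (adjusted p = 0.48 with an estimated correlation). POLE stood at -1.74 ± 0.17, MCM6 at -1.42 ± 0.14 and MCM2 at -1.65 ± 0.19. In G2/M and mitosis 0 were higher, 25 lower and 11 not called (0 higher and 27 lower adjusted over the list alone) of 36, and camera gave adjusted p = 2.41e-12 (adjusted p = 0.48 with an estimated correlation). NEK2 stood at -1.0 ± 0.11 and the transcription factor FOXM1 at -1.19 ± 0.14. Cholesterol synthesis counted 22 genes, of which 0 were higher, 16 lower and 6 not called (0 higher and 19 lower adjusted over the list alone), and camera gave adjusted p = 9.13e-08 (adjusted p = 0.48 with an estimated correlation). LSS (-1.08 ± 0.12) and FDPS (-1.10 ± 0.17) were among those lower. Of 23 genes of the unfolded protein response and amino acid stress 0 were higher, 11 lower and 12 not called (0 higher and 12 lower adjusted over the list alone), and camera gave adjusted p = 4.97e-05 (adjusted p = 0.516 with an estimated correlation). The pseudokinase TRIB3 stood at -1.45 ± 0.20 and asparagine synthetase ASNS at -1.02 ± 0.12.

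Glycolysis and hypoxia genes counted 24, of which 0 were higher, 8 lower and 16 not called (0 higher and 8 lower adjusted over the list alone), and camera gave adjusted p = 0.00531 (adjusted p = 0.657 with an estimated correlation). SLC2A1 stood at -1.20 ± 0.17 and the lactate transporter SLC16A3 at -1.03 ± 0.22. Of 15 ERK MAP kinase output genes 0 were higher, 7 lower and 8 not called (0 higher and 7 lower adjusted over the list alone), and camera gave adjusted p = 0.00328 (adjusted p = 0.48 with an estimated correlation). The phosphatase DUSP5 stood at -1.32 ± 0.15 and FOS at -1.17 ± 0.19, and the list's median of -0.54 was -0.28 without tubule 4 and -0.32 without extension 3. Oxidative phosphorylation had 32 measured genes, of which 0 were higher, 8 lower and 24 not called (0 higher and 11 lower adjusted over the list alone), and camera gave adjusted p = 0.000125 (adjusted p = 0.657 with an estimated correlation). CYC1 stood at -0.80 ± 0.17. In ribosomal proteins 0 were higher, 2 lower and 30 not called (0 higher and 1 lower adjusted over the list alone) of 32, and camera gave adjusted p = 0.00334 (adjusted p = 0.657 with an estimated correlation). RPSA stood at -0.76 ± 0.12, and the ribosomal call ended under quantile normalization and with the deposited values.

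For 20 lists no shift was called (adjusted p between 0.0594 and 0.91), with a median, mean and test that differed in sign for 3 (YAP targets, basement membrane and growth factors). Of the epithelial-mesenchymal list (2 higher and 5 lower of 21, or 2 and 7 adjusted over the list alone), SNAI1 stood at -1.66 ± 0.18 and CDH2 was at least 2.24-fold lower (adjusted p = 0.00104). MMP28 stood at -1.63 ± 0.14 among the proteases (1 higher and 6 lower of 23, or 1 and 6 adjusted over the list alone). SCNN1B (-1.55 ± 0.11) and SLC22A2 (1.59 ± 0.18) changed in the kidney list (6 higher and 6 lower of 31, or 6 and 8 adjusted over the list alone). The chemokine list gave 6 higher and 2 lower of 18 (7 and 2 adjusted over the list alone). Fry called the STAT3, protease, integrin, epithelial-mesenchymal, heat shock, WNT and reference lists downward (adjusted p between 0.00155 and 0.0316), and with slide as a block camera added no call. Common reference genes gave 0 higher and 4 lower of 10 (0 and 5 adjusted over the list alone), with a median of -0.36, further down than that of ribosomal proteins (-0.27) and close to that of oxidative phosphorylation (-0.35). For the reference genes camera made no call (adjusted p = 0.0956, from 0.0447 to 0.516 over the alternatives), and fry did (adjusted p = 0.00218). At tubule over extension and blocked by slide, 9 of the 9 called lists and 53 of the 53 genes named and called were called in the same direction, and 9 lists and 53 genes kept their sign within each of the 3 slides. Here too the sign within slides was fixed for genes named in this contrast by the rule of no overlap. List medians moved by at most 0.06 with the block and by at most 0.23 within a slide, and the genes' log2 changes by at most 0.24 (WDPCP) and 1.77 (CDH2). The call ended under at least 1 other alternative for ribosomal proteins, with adjusted p from 2.43e-17 to 0.695 over the 9 lists. Among the genes, 42 of 53 kept their call under normexp with local background, 53 under normexp with median background and 53 with median centring. Local background ended the calls of BAAT, CDH2, CFTR, EPSTI1, IL1RN, MMP1, PCK1, RASA3, SNAI1, TFAP2C and WDPCP.

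Across both steps, 914 features peaked at extension (394 with a gene symbol) and 1226 dipped there (294 with a gene symbol). MGST1 rose by 3.62 ± 0.19 and then fell by 3.48 ± 0.19, with the tubule stage 0.13 ± 0.19 from the monolayer (adjusted p = 0.66), and TNS4 followed the same course. SLC6A14, CASP4, GCNT1, DSG3, CGREF1, PCK1 and IL1RN also peaked. At extension CGREF1 was at least 3.46-fold (adjusted p = 3.13e-05) and PCK1 at least 2.32-fold higher than in the monolayer (adjusted p = 6.82e-06). IL1RN rose there by 2.21 ± 0.26 (adjusted p = 6.65e-05, 1 of 4 monolayer arrays well above background). RASA3, a regulator of Ras and Rap GTPases, was at least 2.34-fold higher at extension than in the monolayer (adjusted p = 7.62e-05) and at least 2.37-fold lower at tubule than at extension (adjusted p = 0.000184). PDZK1 led the dipping features with a symbol by the smaller of its 2 changes, and DACH1, a transcription cofactor, fell by 2.61 ± 0.14 and rose by 2.45 ± 0.14. CFTR (-1.81 ± 0.32 then 3.01 ± 0.32), TXNIP (-1.97 ± 0.19 then 2.87 ± 0.19), RERG (-1.97 ± 0.18 then 2.81 ± 0.18), TM4SF5 (-2.86 ± 0.20 then 1.78 ± 0.20) and EPSTI1 (-1.83 ± 0.35 then 2.6 ± 0.35) dipped, with 1 of 4 extension arrays well above background for CFTR, RERG and EPSTI1. So did the ciliary genes RPGR (-1.72 ± 0.37 then 2.32 ± 0.37) and WDPCP (-2.0 ± 0.41 then 2.22 ± 0.41), the latter with 1 of 4 extension arrays well above background.

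At the tubule stage 673 of the 914 peaking features and 891 of the 1226 dipping features were not called different from the monolayer. Both contrasts share the extension arrays. With no effect simulated over 20 draws the counts were 0 and 0 (means of 137.5 and 126.7 at limma's unadjusted p under 0.05 in both contrasts). With no feature changed and noise independent between arrays, almost no adjusted calls can arise, so these 0 counts give no support. Independent lists would give 271.1 and 374.4. With the extension arrays split 2 and 2 between the contrasts, the 6 splits gave 392 to 556 peaking features (median 474) and 479 to 838 dipping ones (median 648.5). Over all features the changes of the 2 steps correlated at -0.524, against -0.498 with no effect and a median of -0.361 with the split arrays. With slide as a block 3089 peaked and 2755 dipped, and without slide 3 these were 1553 and 1410. The 1226 dipping features were 814 without monolayer 1 and 747 without extension 3. Other courses were 639 features higher at both later stages and 962 lower at both with no call between these stages, 80 higher and 280 lower at each step, and 789 higher and 855 lower at the tubule stage than at both earlier ones. MME belonged to the features higher at both later stages, and CENPA to those lower at each step. By the same comparison, 915 features were higher and 1346 lower than the monolayer at both later stages, which share the monolayer arrays. No effect gave 0 for each (131.15 and 126.4 at unadjusted p), which again gives no support. Independent lists would give 244.1 and 414.7, and split monolayer arrays gave medians of 492 and 698.

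**Figure D3:**
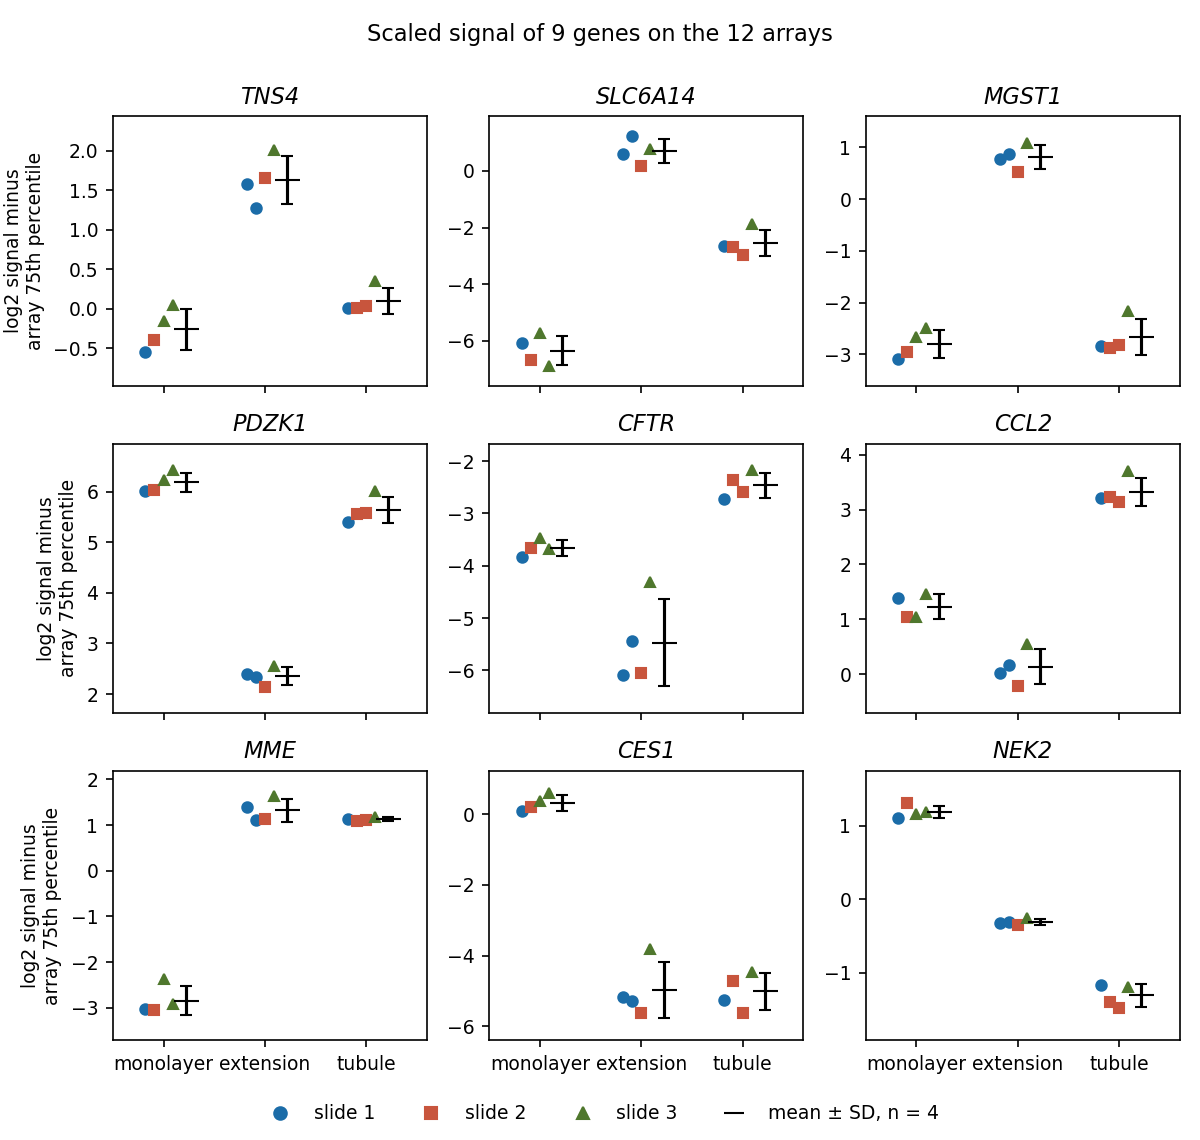
Log2 signal relative to each array's 75th percentile for 9 genes at the 3 stages, with a point per array, marker shape for slide, and mean ± SD (n = 4). TNS4, SLC6A14 and MGST1 peak at extension, PDZK1, CFTR and CCL2 are lowest there, MME stays high at both later stages, and CES1 and NEK2 fall.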

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

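The tests of slide, replicate number and fibroblast collagens were chosen after the results they measure were seen, as were leaving out slide 3 and the unadjusted counts of splits. The arrays of a slide deviated from their stage means in the same direction, which split the 12 arrays by something other than stage. Pairs of arrays of different stages on 1 slide with different replicate numbers had a median correlation of deviations of 0.632 (7 pairs, 0.24 to 0.79), which is consistent with a slide or scan batch. Pairs with 1 replicate number on different slides had a median of -0.533 (4 pairs), but pairs that share neither had -0.26 (29 pairs, -0.81 to 0.41), so deviations on different slides are negative already. The upper bound first set for this test took no account of that and was replaced, after the value was seen, by the lowest of those pairs, which leaves a shared culture day carried by that number open. Pairs on 1 slide with 1 number had 0.53 (8 pairs). Slide or scan, a culture day, or cultures handled together and placed on 1 slide cannot be told apart by these arrays, and no biological explanation was tested. With slide as a block the features lower at tubule than at extension were 6665 and without slide 3 they were 4342, against 2570.

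Single genes of secreted proteins, such as CCL2, CCL7 and MMP1, were higher at the tubule stage than in the monolayer, a grouping made by eye with no list and no test of their number, and human fibroblasts were the other cells of the culture. COL1A1, COL1A2 and COL3A1, abundant in fibroblasts, were well above background on 0 of the 8 co-culture arrays and on 0 of the monolayer arrays. No array thus shows that these dog probes can detect the transcripts. The values therefore cannot tell whether RNA of the human fibroblasts was present. Of the 14 fibroblast list genes with a probe that were not on all monolayer arrays, 2 (COL5A1 and PDGFRA) were on all 4 arrays of a later stage. COL5A1 was already on 3 of 4 monolayer arrays, with 4 at extension and 3 at tubule. PDGFRA was on 0 monolayer arrays, with 3 at extension and 4 at tubule. Another 9 were on no array. No array shows that those 9 probes can detect their transcripts, so they cannot tell whether there was a gain. On all monolayer arrays as well were 9 list genes. A rise of part of the list stays open, since the 11 measured members had a median of 0.45 at extension and 0.23 at the tubule stage against the monolayer and were called upward by fry (adjusted p = 0.000287 and 0.00442), though not by camera (adjusted p = 0.0653 and 0.183). Whether human RNA binds these dog probes was not tested. No biological explanation was tested for these rises.

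Transcripts without a gene symbol made up 76.0% of the features that dipped at extension, 56.9% of those that peaked and 65.9% of those tested. Within 5 strata of mean signal the odds ratio of dipping, without against with a symbol, was 1.65 (1.44 to 1.89), which argues against dim probes alone as the reason. The interval counts features as independent and does not measure the spread between arrays. After quantile normalization the unnamed share among dipping features was still 10.7 percentage points above that of all tested features. The excess thus did not depend on the choice between these 2 scalings, and the share was not computed under median centring. With slide as a block the unnamed share among dipping features was 72.2%. What these transcripts are was not tested, and no biological explanation was tested.

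Other splits of the arrays into stages were counted for each result. Between extension and monolayer 1 of the 35 splits of 8 arrays into 4 and 4, the real one, gave as many calls (5321, highest other 1). The same held for tubule against monolayer (1 of 35, 5510, highest other 0) and tubule against extension (1 of 35, 5455, highest other 0). The real split thus led these adjusted counts among splits that ignore the slides. Other splits mix 2 stages, whose difference adds to the spread within groups and lowers their counts. This lead therefore does not by itself exclude chance. At limma's unadjusted p under 0.05 the real splits gave 8206, 8134 and 8245 features and the highest other splits 5243, 8146 and 5549, so that for tubule against monolayer 2 of 35 splits reach the real unadjusted count and chance is not excluded by it. In each of these 3 other splits the arrays of slide 3 stood together, and for tubule against monolayer, with 8146, that split set monolayer 1, monolayer 3, tubule 4 and monolayer 4 against the others. Blocked by slide, tubule against monolayer gave 4819 features higher and 4757 lower. For peaking and dipping features 1 of 100 draws of 12 arrays into 3 stages, the real one, gave as many (2140), the highest other gave 1588, and 2 of the 99 other draws gave any, both of which kept the 4 tubule arrays together. For the lists 1 of 100 draws, the real one, gave as many calls by camera (34), but the highest other draw gave 33 and the median other draw 18. Estimated correlations within lists ran from -0.025 (fibroblast markers) to 0.682 (oxidative phosphorylation), against the preset 0.01. With them the real stages gave 0 calls, and 5 when slide was also a block. The other draws were not run with them, so whether they account for the calls there was not tested. For peaking and dipping features the real stages led among draws that ignore the slides. Draws that mix stages widen the spread within groups in the same way, so this lead does not by itself exclude chance. For the lists the real value led by 1 call and was 33 without slide 3, so that the count gives no firm exclusion.

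Values far from the other 3 arrays of their stage numbered 33 of 441 groups tested (7.5%), each with a gap, as a share of its stage's range, over Dixon's 95% critical value for 4 arrays. Chance gives about 1 in 20 for exchangeable arrays, which these are not, since arrays of a slide deviate together and the 4 arrays of slide 3 (tubule 4, extension 4, monolayer 3 and monolayer 4) held 25 of the 33 values. Tubule 4 held 15. Its share of probes well above background was 54.2% against 58.7% to 59.0% (0.935), and its genes were TRIB3 (0.929), MGST1 (0.925), CDKN2C (0.919), TNS4 (0.915), SLC2A1 (0.907), SCNN1B (0.894), CD44 (0.888), FZD2 (0.861), SLC16A3 (0.857), FBLN5 (0.854), MET (0.854), CCL8 (0.847), CCL2 (0.837) and RPL7 (0.837). Extension 4 stood apart for AVIL (0.889), ACSL6 (0.871), RASA3 (0.87), GCNT1 (0.859), CENPA (0.852) and MMP1 (0.8295). Extension 2 did so for TPX2 (0.861), DNAI1 (0.85) and SLC22A2 (0.849), and extension 3 for BAAT (0.891). Monolayer 3 had 68 outlier-marked spots against 189 to 208 (0.864) and stood apart for ITGA2 (0.919) and SLC12A2 (0.839). Monolayer 4 had 19 saturated spots against 2 to 3 (0.941), and tubule 2 had 4 against 3 on each of the others (1.0) and stood apart for CLDN7 (0.83). Monolayer 1 was apart for CCND1 (0.881) and monolayer 2 for FGF9 (0.852).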

How the results depend on the processing

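Leaving out slide 3, keeping marked probes, normexp on median background, the estimated correlation with slide as a block and the background of named genes were alternatives chosen as tests after the data were seen. Of the 196 gene and contrast pairs printed and called, 196 kept their call with quantile normalization, the deposited values, no filter, the mean of a gene's probes, the replicate block, slide as a block, trended and robust variance, array weights, 2 stages at a time and without each of the 12 arrays. This follows in part from how pairs were picked for printing, since of the 393 pairs that the rule named and that were called, 360 kept their call without each array, 393 with slide as a block, 383 with quantile normalization, 341 with median centring and 254 with normexp on local background. Printed pairs kept numbered 195 with normexp on median background, 193 with median centring, 194 without slide 3 (ACTA2 and IFIT2 at extension ended) and 151 with normexp on local background (43 ended, 2 turned), and a filter over all 12 arrays tested 147 and kept 147. Of 34 list calls 32 kept theirs with quantile normalization, the deposited values and a filter over all 12 arrays, 33 without a filter, with named genes as background and without monolayer 4, 31 without slide 3, 28 with normexp on local background (5 ended, 1 turned) and 34 with median centring, either block and array weights. Signal over background limits dim genes, where only a bound of the fold is given.

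Counts are in the order extension over and under monolayer, tubule over and under monolayer, and tubule over and under extension, then peaked and dipped. With normexp on local background they were 806, 1179, 696, 1462, 961 and 750, then 236 and 356. Very high local background on 8 spots of monolayer 2 set the fit there (a median of 599.2 after normexp, 116.1 with the median background). Blocked by slide, counts moved by over 1.5 times to 5583, 5006, 4819, 4968 and 6665, then 3089 and 2755, as the block removes variance between slides. The count lower at tubule than in monolayer did not move so far. Median centring gave 1004 higher at extension, 919 higher at tubule over monolayer, 1162 lower at tubule than at extension and 385 that peaked, since it shifts every feature of an array alike. Array weights gave 4035 and 5695 at tubule against monolayer and 5441 lower at tubule than at extension, and the cause was not tested. Without a filter 1684 were lower at tubule than at extension and 792 dipped, with more features tested. Without slide 3 these counts were 4342 lower and 1553 that peaked, and the cause was not tested. By construction a stricter adjusted p under 0.01 left 1256, 1500, 1126, 1799, 1743 and 1194, then 426 and 535, and a change of at least 2-fold left 676, 719, 571, 690, 1118 and 393, then 163 and 288. With the extension arrays split 2 and 2, so with fewer arrays per contrast, 474 peaked.

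With 1 array left out the counts ranged from 1742 to 2709, 1990 to 3321, 1657 to 2551, 2176 to 4071, 2202 to 2962 and 1568 to 3557, then 645 to 1085 and 747 to 1299, and the list calls from 34 to 36. Replicate numbers were not used as pairs, since correlations of the 12 pairs ran from -0.69 to 0.75 with 8 of 12 over 0.1, which leaves open whether a number marks a shared day, and 7 of 12 arrays were nearest to one of their own number and 11 to one of their own slide. With the replicate block 4375 were lower at tubule than at extension and 1558 peaked, and the list calls were 35. List calls by camera fell from 34 to 0 with an estimated correlation (6, 4 and 1 of 29 lists per contrast at an unadjusted p under 0.05, and 42 calls of 87 by fry) and to 5 when slide was also a block. The estimates ran from -0.025 to 0.682, against the preset 0.01, and a higher correlation raises p in this test. Why 5 calls were made with the block was not tested. Under normexp on local background the set test of the ribosomal list turned upward at tubule over monolayer (median -0.0138 against -0.18, adjusted p = 0.751, 0.00114 to 0.759 over the alternatives). The sign turned for PDGFRA at extension (-8e-04, adjusted p = 0.999, from 0.000424 to 0.999) and at tubule over monolayer (-0.3688, adjusted p = 0.518, from 0.00158 to 0.518). On monolayer 2 that fit was set by 8 spots, as given above. With normexp on median background 0 of the 34 list calls and 0 of the 196 printed pairs turned. PDGFRA did lose its call there at tubule over monolayer. The cause was not tested further.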

Other observations

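Of the tests in this part, leaving out slide 3 was chosen after the data were seen. Single genes changed in lists whose set test made no call. In the TGF-beta and BMP pathway, which gave 4 higher and 5 lower of 35 (4 and 5 adjusted over the list alone) at the tubule stage, the activin antagonist FST fell by 1.51 ± 0.21 at extension and stood at -2.09 ± 0.21 at the tubule stage on the log2 scale (SE, n = 4 arrays per stage, adjusted p = 0.000261 and 1.84e-05 against the monolayer). The ligand BMP4 (-1.02 ± 0.14 and -1.32 ± 0.14, adjusted p = 0.000219 and 2.75e-05) and the BMP-responsive inhibitor ID3 (-1.23 ± 0.19 and -1.72 ± 0.19, adjusted p = 0.000462 and 3.35e-05) were lower at both later stages. Of the YAP targets (3 higher and 2 lower of 14, or 3 and 5 adjusted over the list alone at the tubule stage), tissue factor F3 (array name TF) was higher at extension and at the tubule stage than in the monolayer, by 1.81 ± 0.11 and 0.90 ± 0.11 (adjusted p = 3.23e-07 and 0.00011). In the growth factor list (5 higher and 1 lower of 22, or 5 and 1 adjusted over the list alone at tubule over extension), the ligand FGF9 fell by 1.14 ± 0.13 at extension (adjusted p = 3.99e-05) and rose by 1.03 ± 0.13 from extension to tubule (adjusted p = 0.000135).

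Interferon response genes gave 5 higher and 1 lower of 18 (5 and 1 adjusted over the list alone) at the tubule stage and 4 higher and 1 lower of 18 (4 and 1 adjusted over the list alone) at tubule over extension. The ubiquitin-like modifier ligase HERC5 rose by 1.84 ± 0.16 from extension to tubule (adjusted p = 1.42e-05), and IFIT2 was higher than in the monolayer at extension, by 1.29 ± 0.29, and at the tubule stage, by 1.69 ± 0.29 (adjusted p = 0.00728 and 0.00128). The call of IFIT2 at extension ended without slide 3. In the actin, contractility and migration list (3 higher and 2 lower of 25, or 3 and 2 adjusted over the list alone at the tubule stage), calponin CNN3 was higher at extension, by 1.38 ± 0.15 (adjusted p = 3.91e-05), and at the tubule stage, by 1.03 ± 0.15 (adjusted p = 0.000391). The Crumbs complex protein PATJ of the polarity list (3 higher and 8 lower of 33, or 3 and 8 adjusted over the list alone at tubule over extension) fell by 0.96 ± 0.16 at extension (adjusted p = 0.00114) and rose by 1.63 ± 0.16 afterwards (adjusted p = 3.87e-05). Heat shock and oxidative stress genes gave 1 higher and 8 lower of 18 (2 and 8 adjusted over the list alone) at the tubule stage, with the metallothionein MT2A at -1.20 ± 0.09 (adjusted p = 1.93e-06). Among p53 targets and cell cycle inhibitors (2 higher and 4 lower of 20, or 2 and 4 adjusted over the list alone at the tubule stage) the CDK inhibitor CDKN2C stood at -0.85 ± 0.17 at extension and -1.16 ± 0.17 at the tubule stage (adjusted p = 0.004 and 0.000439).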
